A study of Drosophila melanogaster with 3 samples.

How the data were processed

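Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Ultrabithorax (Ubx), a Hox transcription factor that sets segment identity along the body axis, sits on the genome of Drosophila S2-DRSC cells. S2-DRSC is a fly cell line of late embryonic origin, and the cells used here carried a stably integrated Ubx with an HA epitope tag. Per the labels, the cells were kept in 10 micromolar copper sulphate for 24 h before chromatin was prepared. The series holds 3 samples, namely 2 replicates of an immunoprecipitation with an antibody against HA and 1 input sample. It is not stated whether the replicates came from separate cultures.

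The values analysed were 1 list of peaks, which the descriptions of both immunoprecipitation replicates name. Each row of the list gave a sequence name, a start, an end, a peak name and a score deposited by the authors. The file had no header, and the sources used here do not say which quantity of the peak caller the score is. The submitters' processing notes name the aligner BWA 0.7.12, the peak caller MACS2 and the genome build dm3. How the replicates were combined, how the input was used and which thresholds applied are not given in the sources used here. Because both replicates share 1 list, no value had a replicate error, and no comparison between replicates or between the immunoprecipitation and the input could be made. Read counts and signal per sample were not analysed here, so the depth behind each peak is unknown. The Poisson, Wilson and exact intervals below cover counting error only. These intervals, the bootstrap intervals of medians and the permutation tests of medians treat peaks as independent, which closely spaced peaks are not. The p-values of those tests therefore cover the spread among the peaks of this list only. The bootstrap over 1 Mb bins resamples whole bins, but it was not used for the medians of scores and widths.

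The build was checked against the reference genome held for this work, Release 6 (dm6). The names U, Uextra and those ending in Het occur in the peak list and not among the chromosome names of Release 6. On 2R the last peak ended 4.14 Mb before the end of the Release 6 arm, and on 3R it ended 4.17 Mb before it. The list was therefore taken as dm3 throughout, and no coordinate was converted. A dm3 genome or gene annotation was not used here, so peaks are given by position, and no gene, exon, intron or promoter is assigned to them. The planned comparisons of promoters, location classes, gene lists and sequence motifs needed such an annotation and were not made. As planned for that case, the named items are the 10 peaks with the highest score, by coordinate. The widest peaks, the windows with the most peaks and the longest stretches without a peak were named in addition, after their values were seen.

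Coordinates are 1-based dm3 positions. Lengths of the arms in dm3 were not used, so peak density was calculated over the span from the first to the last peak of an arm, with an exact Poisson 95% interval. Shares of peaks carry Wilson 95% intervals. The ratio of X to the 4 large autosomal arms (2L, 2R, 3L and 3R) has an exact 95% interval conditional on the total, and a second interval from a bootstrap over 1 Mb bins. Spacing was the share of peaks whose midpoint lay within 5000 bp of another midpoint. It was compared with 10000 random placements of the same number of midpoints over the span of each sequence, in a two-sided permutation test whose smallest possible p is 0.0002. Sequences with a single peak were left out of this test. Random placements used all positions of the span, whether or not reads can be mapped there. The number of peaks per 100 kb window was compared with placements of the same kind on the 6 arms. Median scores and widths of sequence classes were compared by two-sided permutation tests with 100000 resamples, adjusted by Benjamini-Hochberg over the 10 tests, with bootstrap 95% intervals of the difference from 2000 resamples. These last tests, the windows and the bins at the centromeric ends of the arms were chosen after the list had been seen. The counts per arm and the spacing test were fixed before the data were examined.

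The tests were tried on simulated data. With the real number of peaks per arm (9528 in all) placed at random, 3 of 40 runs of the spacing test gave a p under 0.05. With 2% of the peaks moved next to another, 12 of 20 runs did, and with 5% moved, 20 of 20 runs did. For 600 simulated scores against 9000, the median test gave a p under 0.05 in 2 of 40 runs without a shift and in 20 of 20 runs with a shift of 5 score units. Groups as small as the 61, 90 and 125 peaks compared below, smaller shifts and widths were not simulated. How often the test would detect a difference there is unknown. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The alternatives were the 50% and the 25% of peaks with the highest score, the 6 arms alone, joining of peaks less than 1000 bp apart, other spacing distances, gaps between peak edges, placement inside 100 kb bins, and leaving out peaks with a score under 5 or a score that is visibly a mean.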

Results

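The genomic binding of HA-tagged Ubx was profiled in S2-DRSC cells to find the regions that this Hox protein occupies when it is expressed there. The peak list deposited by the authors held 10337 HA-Ubx peaks for the 2 immunoprecipitation replicates together. Of these, 9528 peaks (92.2%) lay on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. A further 90 peaks lay on the sequences of the dm3 build named Het, 125 on the sequence named U and 594 on the sequence named Uextra, the last being 5.75% of the list. The peaks covered 8.12 Mb in all and had a median width of 616 bp, with an interquartile range of 427 to 961 bp. Widths ran from 177 to 6890 bp. The median score was 24.9, with an interquartile range of 16.4 to 38.5 and a maximum of 174. Across peaks, which are not independent replicates, wider peaks had higher scores, with a Spearman rho of 0.22 and a Pearson r of 0.17 (permutation p = 0.0001 for each, the smallest that the permutations can give).

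The 10 peaks with the highest score were spread over 5 arms, with 3 on 2L, 3 on 3R, 2 on 3L, 1 on 2R and 1 on X. The highest score, 174, was shared by a peak of 1637 bp on 2L at 14533807 to 14535443 and a peak of 1661 bp on 3R at 26667343 to 26669003. Neither had another midpoint within 5000 bp, and the nearest other peaks were 7035 bp and 24746 bp away. The next was a peak of 2521 bp on 3L at 7624514 to 7627034, with a score of 166. It was followed by a peak of 877 bp on 2R at 3316597 to 3317473, which scored 139. A peak of 619 bp on 3R at 11862854 to 11863472 scored 138 and stood in a group, with 4 other midpoints within 5000 bp. The highest-scoring peak of X, at 19179221 to 19180660, scored 135 and had 1 other midpoint within 5000 bp. The remaining 4 of the 10 scored between 119 and 129. They lay on 3R at 26287468 to 26288090, on 2L at 14515094 to 14516671, on 3L at 14355741 to 14356214 and on 2L at 11447383 to 11448102.

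The widest peaks were not those with the highest scores. The widest, at 2729514 to 2736403 on 2L, measured 6890 bp and scored 24.8. The second, at 1129948 to 1135570 on 3R, measured 5623 bp and scored 17.2. Peaks of 5496 bp on 3R at 5753826 to 5759321 and of 5418 bp on 2R at 2515413 to 2520830 scored 63.6 and 62.2. A peak of 5469 bp lay at the very start of 2L, from 23 to 5491, with a score of 30.1.

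The arms differed in peak density. Arm 3L had the highest density, 89.5 peaks per Mb (95% Poisson interval 85.8 to 93.3, 2190 peaks). It was followed by 2R with 86.4 peaks per Mb (82.5 to 90.4, 1826 peaks), 3R with 83.1 (79.8 to 86.6, 2318 peaks) and 2L with 77.8 (74.2 to 81.4, 1789 peaks). The X chromosome had 60.3 peaks per Mb (57.2 to 63.6, 1344 peaks), and its interval lay below that of each of these 4 arms. The small chromosome 4 had 61 peaks, or 47.5 per Mb (36.3 to 61.02). Set against the 4 large autosomal arms together, which had 84.2 peaks per Mb (82.4 to 86.0), the density on X was 0.717 times as high (exact 95% interval 0.676 to 0.759). Resampling 1 Mb bins, which allows for uneven density along the arms, gave an interval of 0.608 to 0.822. The part of the span covered by peaks was 4.61% on X and 6.87% on the 4 large autosomal arms. No input signal was analysed here, so the densities are not corrected for the number of reads each arm received. The number of copies of each arm in these cells was not examined either.

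**Figure D1:**
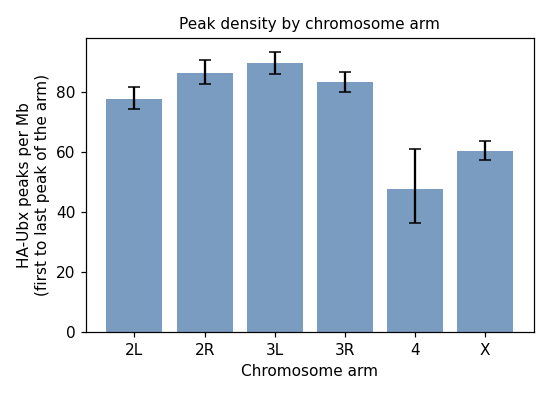
HA-Ubx peaks per Mb (vertical axis, over the span from the first to the last peak) for each chromosome arm (horizontal axis), with bars for the density and error bars for the exact 95% Poisson interval. X, at 60.3 peaks per Mb, and 4, at 47.5, lie below the 4 large autosomal arms, which range from 77.8 to 89.5.

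The X-to-autosome ratio was lower among strong peaks. In the 50% of peaks with the highest score it was 0.666 (exact 95% interval 0.612 to 0.724), and in the top 25%, an alternative chosen after the data were seen, it was 0.592 (0.522 to 0.668). The ratio in the top 25% was 0.826 times that over the whole list (95% interval from a bootstrap over 1 Mb bins 0.709 to 0.951). Peaks on X had a median score of 24.2, against 25.5 on the 4 large autosomal arms. The difference of -1.31 (bootstrap 95% interval -2.79 to -0.42) passed the permutation test (adjusted p = 0.033). X peaks were also narrower, with a median of 608 bp against 642 bp (difference -34.0 bp, -71.5 to -9.5, adjusted p = 0.023, permutation test). On chromosome 4 the peaks were narrower still, with a median of 432 bp (difference from the large autosomal arms -210.0 bp, -291 to -88.9, adjusted p = 0.0077, permutation test). Their median score of 31.4 was above the 25.5 of the large autosomal arms (adjusted p = 0.033, permutation test), but the bootstrap interval of the difference ran from -5.34 to 9.76 and included no difference.

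Peak density was low at the centromeric end of the dm3 sequence on some arms and not on others. The L arms and X are numbered towards the centromere, and the R arms away from it. How far the end of each dm3 arm lies from its centromere was not examined, and the distance may differ between arms. In the complete 1 Mb bin nearest to the centromere, 2L had 26 peaks (22000001 to 23000000, 95% Poisson interval 17.0 to 38.1), against a median of 83 peaks per bin over that arm. The corresponding bin of 2R had 25 peaks (1 to 1000000, 16.2 to 36.9) against a median of 85, and that of 3L had 15 (23000001 to 24000000, 8.40 to 24.7) against a median of 89.5. On each of these 3 arms no other complete bin held fewer peaks. On 3R the bin nearest to the centromere had 89 peaks (71.5 to 110), above the arm's median of 79, and 16 of its 27 bins held fewer. On X that bin had 48 peaks (35.4 to 63.6) against a median of 63, and 6 of 22 bins held fewer. The median score in these bins was 15.9 on 3L, against 25.4 over the whole arm. It was 20.5 against 25.1 on 2R, 23.5 against 25.5 on 2L, 25.003 against 25.904 on 3R and 21.9 against 24.2 on X, and these differences were not tested. How much of each bin reads can be mapped to was not examined, so fewer peaks in a bin need not mean less binding there.

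Peaks on the Het and Uextra sequences scored lower and were narrower than those on the arms, and peaks on U were narrower. On the Het sequences, which hold mapped heterochromatin, 37 peaks lay on 3RHet, 22 on 2RHet, 22 on 3LHet, 7 on 2LHet, 1 on XHet and 1 on YHet. Their median score of 19.0 was lower than the 25.2 of the arms (difference -6.27, bootstrap 95% interval -8.79 to -3.78, adjusted p = 0.0085, permutation test). Their median width of 469.5 bp was below the 637 bp of the arms (difference -167.5 bp, -206 to -113, adjusted p = 0.0077, permutation test). The 594 Uextra peaks, on a sequence that joins unplaced scaffolds, had a median score of 22.8 (difference from the arms -2.45, -4.07 to -1.60, adjusted p = 0.0077, permutation test) and a median width of 467 bp (difference -170.0 bp, -190 to -150.5, adjusted p = 0.0001, permutation test). The strongest Uextra peak scored 114, and 2 of the 25 peaks with the highest score in the list were on Uextra. The 125 U peaks were narrower, with a median of 517 bp (bootstrap interval of the difference from the arms -157 to -94.0 bp, adjusted p = 0.012, permutation test). Their median score of 22.4 did not pass the test (difference -2.85, -4.54 to -0.71, adjusted p = 0.12, permutation test). How much of the Het, U and Uextra sequences reads can be mapped to, and how long their scaffolds are, was not examined. Narrower or lower-scoring peaks on them therefore need not mean a difference in binding.

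**Figure D2:**
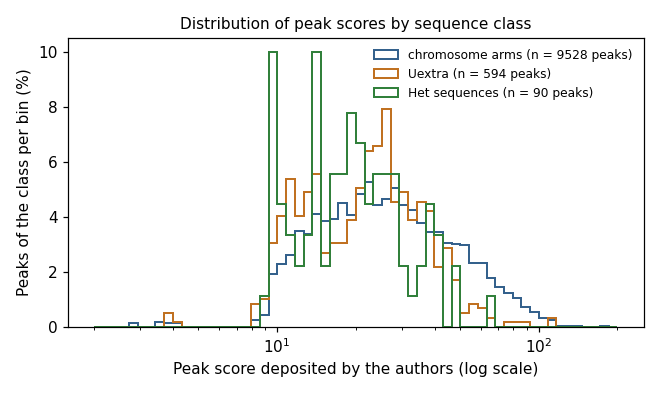
Distribution of the peak score deposited by the authors (horizontal axis, log scale) as the share of peaks in each of 3 sequence classes (vertical axis, percent of the class per bin), with lines for the arms, Uextra and the Het sequences. The Het peaks lie lower, with a median of 19.0 against 25.2 on the arms, and a small group of peaks scores under 5, apart from the rest.

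HA-Ubx peaks lay close to one another. Of the 10335 peaks on sequences with more than 1 peak, 70.4% had another midpoint within 5000 bp. Random placement of the same peaks gave a median of 52.2% (central 95% of placements 51.1% to 53.3%), so the observed share was 1.35 times the random one (two-sided permutation test, p = 0.0002, the smallest that 10000 placements can give). Within 1000 bp the share was 17.5%, against 14.0% at random (13.1% to 14.9%, permutation p = 0.0002). Within 20000 bp, where nearly every random peak also has a neighbour, it was 93.0% against 92.2% (91.8% to 92.7%, permutation p = 0.003). On the arms, the median gap between the edges of adjacent peaks was 3.91 kb, with an interquartile range of 0.9 to 11.7 kb, and the smallest gap was 41 bp. Among the 50% of peaks with the highest score, the share with a neighbour within 5000 bp was 50.5% against 32.1% at random, a ratio of 1.57 (permutation p = 0.0002). With fewer peaks the random share is lower, so this ratio does not show that strong peaks lie closer together than the full list.

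The close spacing showed as windows with many peaks and stretches without any. Over 1207 windows of 100 kb the median was 7 peaks. The fullest window, on 3R at 12000001 to 12100000, held 34 peaks, which covered 30.1 kb and had a median score of 48.7. A window on 3L at 17900001 to 18000000 held 33 peaks with a median score of 34.4. The windows on 3L at 3400001 to 3500000 and at 11200001 to 11300000 held 31 each. These 4 windows exceeded the highest count, 29, seen in any window of the 10000 random placements. Windows on 3L at 600001 to 700000 and on 3R at 17400001 to 17500000 held 29 peaks each, and the fullest window of X, at 12600001 to 12700000, held 28. In all, 16 windows held more than 23 peaks, which was the upper end of the central 95% of the fullest window in random placements. No peak fell in 71 windows (5.88%), against a median of 3 windows at random (0 to 6 in the central 95%). The placements used every position of the span, so windows to which few reads can be mapped were not left out. Among the gaps between adjacent peaks on the 6 arms, the longest was 441 kb on X, from 11923285 to 12364089. The next were 342 kb on 3L, from 13496058 to 13838459, and 332 kb on 2L, from 16910403 to 17242411.

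**Figure D3:**
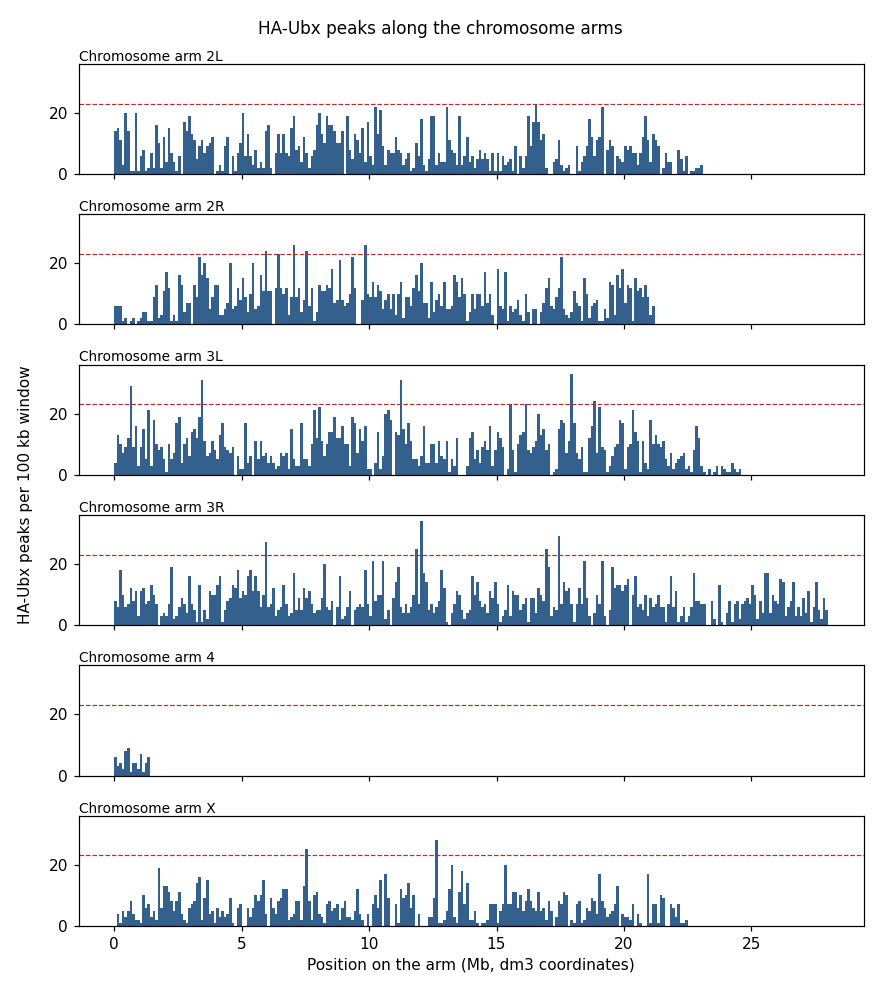
HA-Ubx peaks in each 100 kb window (vertical axis) along the 6 chromosome arms (horizontal axis, Mb in dm3 coordinates), with bars for the counts and a dashed line at 23, the upper end of the central 95% of the fullest window in random placements. The fullest window, with 34 peaks, is on 3R at 12000001 to 12100000, and 2L, 2R and 3L thin out at their centromeric ends.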

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

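The full list of 10337 peaks fell to 5168 in the 50% with the highest score, by construction, and stayed within 1.5 times of the full count on the arms alone (9528) and without the 61 peaks scoring under 5 (10276). The X-to-autosome ratio of peak density went from 0.717 to 0.666 in the 50% with the highest score, which is outside its exact interval (0.676 to 0.759) but inside the one from 1 Mb bins (0.608 to 0.822). In the top 25% it was 0.592, outside both, and the test of read depth on X made with that setting left the cause undecided. It was 0.742 after peaks less than 1000 bp apart were joined and 0.719 without the lowest scores. The excess of close neighbours kept its direction and its p under 0.05 in each of the settings run, with ratios from 1.01 (within 20000 bp) to 1.57 (50% with the highest score). These ratios depend on the random share, which changes with the number of peaks and the distance. Their sizes are not comparable where those differ. The 10 comparisons of score and width between sequences kept their direction and their side of the threshold in 20 of 20 recalculations without the lowest scores or without visibly averaged scores. Settings that need a gene annotation or sequence of dm3 were not run, which covers promoters, location classes, strength at promoters, gene lists and motifs. No replicate could be left out, because the list is common to both, and the depth of each library is unknown. No paired analysis was possible because the replicates share 1 list of peaks. The top 25%, joining before the spacing test, placement inside 100 kb bins, edge gaps, arms alone in the spacing test and the settings without low or averaged scores were chosen after seeing the data.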

Other observations

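The tests of the 3 patterns below were set out before their results were seen, although the patterns themselves were found in the same list. No biological explanation was tested, since the list holds no second group.

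The lower density of HA-Ubx peaks on X was set against 2 technical explanations. Joining of close peaks into wider ones on X would leave the covered length per Mb as high as on the 4 large autosomal arms, but it was 0.671 times as high (95% interval over 1 Mb bins 0.556 to 0.784), which argues against it. If the score grows with read depth, as a significance value does, a lower depth on X would lower every X score and deepen the deficit among strong peaks. Which quantity the score is remains unknown, and a fold enrichment over input need not behave so. The X-to-autosome ratio in the top 25% by score was 0.826 times that over the whole list (0.709 to 0.951), which goes in that direction but falls between the bounds set beforehand (under 0.8 and above 0.9). Depth and a real difference in binding on X therefore cannot be told apart here, and the read coverage of the input on X is the value that a follow-up would need.

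The close spacing of peaks was tested in the same way. If single bound regions had been reported as several peaks, joining peaks less than 1000 bp apart would remove the excess. After joining, the share with a neighbour within 5000 bp was still 46.7% against 41.96% at random, a ratio of 1.11. This argues against splitting of peaks less than 1000 bp apart as the whole cause. Joined peaks cannot have edges under 1000 bp apart, whereas random midpoints can fall at any distance. The fall from the ratio of 1.35 therefore does not measure the part due to splitting. Uneven density at the scale of 100 kb was removed by placing each peak at random inside its own 100 kb bin, and the ratio on the arms was then 1.18, against 1.34 for placement over the whole arm. Neither splitting of peaks less than 1000 bp apart nor uneven density at the scale of 100 kb alone accounts for the excess. Splitting into parts farther apart was not tested by joining. Joining and placement inside bins were not combined, so whether both together would remove the excess is unknown. Grouping around promoters or enhancers, which needs an annotation of the same build, was not tested and also remains open.

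Adjacent peaks on the arms had slightly similar scores. Over 9522 adjacent pairs, Spearman's rho was 0.040 and Pearson's r 0.065 (permutation within arms, adjusted p = 0.0004 and 0.00013, over 4 relations). Pairs with midpoints within 5000 bp gave a rho of 0.073 and an r of 0.10, and pairs farther apart gave a rho of 0.0032, inside the central 95% of permuted scores (-0.028 to 0.029), and an r of 0.024 (adjusted p = 0.10, permutation test). A candidate explanation, whose prediction was met, is that parts of 1 bound region were reported as several peaks. Neighbouring sites with like occupancy would look the same. The limit of 5000 bp also takes in pairs farther apart than the 1000 bp used for joining. The result therefore cannot tell these explanations apart. Differences in depth or accessibility at the scale of 1 Mb are argued against as the whole cause, since the rho of 0.040 lay above the central 95% of scores permuted inside 1 Mb bins (-0.0085 to 0.031, p = 0.0017), although the highest of the 10000 permutations reached 0.048, and the use of the central 95% as the bound was settled after this value was seen. Each of these correlations is small and is across peaks, which are not independent replicates.

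The score column had a structure that a user of the list would want to know. It held 61 peaks with scores from 2.21 to 4.14, then none up to 8.36, above which all other scores lay. Those 61 peaks had a median width of 367 bp, against 467 bp for the 281 peaks with scores from 5 to 10, and 57 of them were on the arms. Of all peaks, 4250 (41.1%) shared their exact score with another peak, and 28 peaks had the score 22.33. At least 328 scores (3.17%) had decimals that only a mean of several values with 5 decimals gives, and the highest number of values that a score needed was 11. Those peaks were wider, with a median of 1238.5 bp against 602 bp, and their median score was 21.9 against 25.1.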
